A study of Homo sapiens with 3 samples.

How the data were processed

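The assay was reverse transcription quantitative PCR on SUM149, an established human breast cancer cell line that the labels describe as ductal carcinoma, negative for the estrogen receptor, the progesterone receptor and HER2. The labels describe 3 repeats of the line, with no treatment, and no other group. They do not say whether a repeat was a separate culture, a separate cDNA or a repeat well, so every SD and p-value measures only the spread between these repeats, which may be technical. Per the labels' protocols, total RNA was isolated with TRI-Reagent, reverse transcribed, and amplified with a SYBR Green master mix over 40 cycles on an Eppendorf instrument, with a melting curve for each reaction. The rule for setting the threshold, the number of wells behind a value, the primer efficiencies and a control without reverse transcriptase are not given in the sources used here.

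The authors deposited 2 tables of the same 179 genes in 3 columns lettered A, B and C. The letters were not matched to the numbered repeats, so a column was used only as a repeat of the group. The first table holds threshold cycles (Ct, the PCR cycle at which fluorescence crosses a set level, so that a lower Ct means more template). The second table, also as deposited by the authors, holds normalized relative levels. From the values, each level equals 100 × 2 to the power of a fixed reference Ct minus the Ct of the gene. The reference Ct took 2 values only. It was 14.09 for ACTB and 78 receptor rows, which equals the mean of the 3 listed ACTB Ct values, and 15.14 for 90 ligand rows, for which no reference measurement was found in the tables. Both were the same in columns A, B and C. The deposited levels therefore correct for a difference of 1.05 cycles between the gene sets and not for differences in input between columns. A ligand and its receptor were tested on the assumption that column letters match across the sets. How the reference Ct values were chosen is not stated per the file headers. The plan had assumed a reference gene that cancels between a ligand and its receptor; that assumption was not met, and the authors' levels were used as deposited.

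The gene sets were taken from these reference values. The 10 rows written as ND in every column have no reference, and were placed by the role of the gene. Of the 179 symbols, 174 matched a current RefSeq symbol (GRCh38.p14 table), 4 matched a synonym and 1 matched neither. IL2R and IL3R were read as the alpha chains and NOTCH as NOTCH1, as their description column states. In the deposited annotation 4 rows share a primer name with another row (IL2 with IL2R, PROK1 with PRKAR1A), FGFR2 carries a primer name that reads FGFR1, and WNT3 one that reads Wnt-3a, so which transcript these 6 rows measured is uncertain. Some other primer names, such as those of GH2 and several interleukin receptors, do not state the gene copy or the chain. No genome build is named, and no coordinates are given.

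A gene was called detected at a Ct of 35 or less in all 3 columns. Levels are given as the mean ± SD of the authors' relative level or of Ct (n = 3 columns), and differences between genes are in PCR cycles (log2 units), which assumes that each primer pair doubles its product in each cycle. PCR without a count of molecules gives no depth or counting interval, and the 3 columns limit the precision. Ligand and receptor levels were compared for pairs from a list of 142 known pairs, of which 77 were measured and 64 had both genes detected. The difference per column was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over the 64 pairs, threshold 0.05). An exact sign permutation of 3 columns cannot give a p below 0.25. Pairs that share a gene are not independent. The medians of the detected ligands and receptors were compared by a two-sided permutation test over genes with 100000 resamples, in which genes are not independent replicates. Of 36 gene lists, 23 had at least 3 detected members. The median log2 level of each was placed as a percentile among 10000 random lists of the same size drawn from the detected genes, which describes this panel and is not a test between conditions.

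The genes named were the 10 highest and 8 lowest detected genes, those not detected in any column, the 3 with the largest SD, the reference gene, the highest and lowest member of each list placed, the VEGF family in full, all measured markers of other cell types, and the 6 largest differences in each direction among pairs past the threshold. Other genes named were chosen after their values were seen: members of a list or pair given as further examples, and all genes in the closing section. The lists, pairs, tests and most alternatives were fixed before the data were examined. The alternatives were other Ct limits (32, 38 or none), undetected values set to a Ct of 40, normalization to the panel median, an amplification factor of 1.9 per cycle, means in place of medians, other limma settings including a minimum difference of 2 cycles, and leaving out each column in turn. On simulated data with the spreads of the 64 pairs, limma called 29.9% of differences of 1 cycle, 65.5% of 2 cycles, 89.7% of 4 cycles and 99.3% of 8 cycles, and 2.46% of all calls were false. On simulated levels of the 157 detected genes, 4% of unshifted random lists of 7 genes fell outside the central 95%, and 71.5% of lists raised by 6 cycles lay above it. The class permutation test called 6% of comparisons without a shift and 76% with the ligands raised by 3 cycles. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.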

Results

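Transcripts of 178 cytokines, growth factors, hormones and their receptors, with ACTB (beta-actin) as reference, were measured by quantitative PCR in SUM149 cells, a triple-negative breast cancer line. The panel was built around mediators linked to tumour vessels and metastasis, and the design asks which of them the line expresses at baseline. Each gene had 3 values, in columns A, B and C, except for 10 genes written as ND in every column. All samples belong to 1 group, so the comparisons lie between genes of the same cells. Values are means ± SD over the 3 columns, and relative levels are those of the authors, on which the reference equals 100.

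Most of the panel was detected, and the 10 highest relative levels were those of ligands. Of 178 genes, 157 were detected at a Ct of 35 or less in all columns, 81 of 98 ligands and 76 of 80 receptors. Among the detected genes 20 ligands and 21 receptors had a mean Ct over 30. Without a control lacking reverse transcriptase, such late values cannot be told apart from background. CXCL1, a neutrophil-attracting chemokine, had the highest relative level, 38.7 ± 16.3, at a Ct of 16.6 ± 0.63. FSHB, the beta subunit of the pituitary hormone FSH, followed at 27.9 ± 0.97, and VEGFC, a growth factor for lymphatic vessels, at 13.1 ± 0.32. MIF, a proinflammatory cytokine, stood at 12.1 ± 3.5, TGFB1 at 9.16 ± 2.8, and INHBA, a subunit of activin A, at 8.90 ± 1.4. The chemokines CCL20 (7.94 ± 1.7), CXCL16 (5.94 ± 2.7) and CXCL8 (5.85 ± 2.6) and the cytokine CLCF1 (6.15 ± 2.7) completed the 10 highest genes. By Ct alone, without the separate reference of each set, TNFRSF1A, the main receptor of TNF (18.6 ± 0.089), and PRKAR1A, a kinase subunit whose row shares a primer name with PROK1 (18.6 ± 0.11), ranked among the 10 earliest genes. From CLCF1 to CXCL8 the levels differed by less than the spread between columns. ACTB itself had a Ct of 14.1 ± 0.14.

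At the other end, CCL7, IL1RL1, CCR4, CCL11, CCL18, IL2R, CX3CR1 and CCL28 were the 8 lowest detected genes by relative level. Their mean Ct values ran from 31.8 for CX3CR1 and IL2R to 33.9 for CCL7, the last at a relative level of 0.00024 ± 0.00011. By Ct alone, CXCL6 (32.4) and CCL21 (32.3) replaced CX3CR1 and IL2R among the 8 latest detected genes. The row for IL2R shares its primer name with IL2, so its identity is uncertain. CCL4, IFNG, IGF1, IL11, IL13, PRL, TNFSF11 (RANKL), WNT3, IL3R and FGFR2 had no value in any column, and GH2 exceeded a Ct of 35 in all 3. The primer name of FGFR2 reads FGFR1 and that of WNT3 reads Wnt-3a, so the identity of both rows is uncertain. The other 10 undetected genes were within the limit in 1 or 2 columns. They included CXCL12, the ligand of CXCR4, with Ct values of 37.8, 36.2 and 34.5.

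Among the VEGF family, VEGFC stood far above the rest. VEGFA, the main growth factor for blood vessels, was detected late, at a Ct of 30.01 ± 0.61 and a relative level of 0.00353 ± 0.0013. VEGFC exceeded VEGFA by 11.94 ± 0.63 cycles. The mean Ct of VEGFA lay just over 30, where background cannot be told apart, and primer efficiencies are not given. The size of this difference, and a low level of VEGFA itself, are therefore uncertain. VEGFD varied most of all detected genes, with Ct values of 27.5, 28.6 and 32.6 (SD 2.66). The receptors were low: KDR (VEGFR2) at a Ct of 28.0 ± 0.28, FLT4 (VEGFR3) at 28.97 ± 0.72 and FLT1 (VEGFR1) at 30.8 ± 0.54. The co-receptor NRP2 was the highest, at 25.7 ± 0.044, and exceeded FLT1 by 5.05 ± 0.55 cycles. Of the angiopoietins, which act on the endothelial receptor TEK, ANGPT1 had a relative level of 0.383 ± 0.23 and ANGPT2 of 0.108 ± 0.052, against 0.00147 ± 0.00044 for TEK.

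The chemokines split by family. All 5 measured ELR+ CXC chemokines, a group that attracts neutrophils and promotes vessel growth, were detected, and their median relative level lay at percentile 99.6 of random lists of 5 panel genes. CXCL1, CXCL8 and CXCL3 (3.75 ± 0.90) carried that rank, while CXCL5 (0.0119 ± 0.0017) and CXCL6 were low, and CXCL1 exceeded CXCL6 by 15.84 ± 2.02 cycles. With the mean in place of the median the list lay at percentile 96.8, inside the central 95%. CC chemokines formed one of the lowest lists, at percentile 0.87, with 13 of 18 members detected. CCL20 was the exception and exceeded the lowest, CCL7, by 15.07 ± 0.67 cycles, whereas CCL2, which attracts monocytes, reached 0.00875 ± 0.0037. The remaining chemokines, with 7 of 9 detected, lay at percentile 30.4 and ranged from CXCL16 down to XCL1 (0.00139 ± 0.0011). Without column C they lay at percentile 18.4, and the CC chemokines lay between 0.090 and 0.22 with each column left out in turn.

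All 7 CC chemokine receptors were detected within a narrow band, from CCR3 at a Ct of 29.8 ± 0.092 to CCR4 at 32.3 ± 0.37. Their median lay at percentile 1.1. The 8 CXC and related receptors were spread more widely, at percentile 44.1. CXCR5 was the highest at a Ct of 24.7 ± 0.059, followed by CXCR1 at 24.8 ± 0.10, CXCR4 at 25.4 ± 0.090 and CXCR2 at 25.8 ± 0.24. CX3CR1 was the lowest.

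The listed ligands of the TGF-beta family had the highest median of any list, with all 4 detected, at percentile 99.9. TGFB1 and INHBA were followed by TGFB2 at 5.66 ± 3.5 and BMP2 at 0.619 ± 0.079, and TGFB1 exceeded BMP2 by 3.84 ± 0.43 cycles. The 4 listed receptors lay at percentile 91.7, from TGFBR2 (1.71 ± 0.088) down to TGFBR3 (0.0117 ± 0.0016). The lists leave out INHBB (0.196 ± 0.23), lower than the 4 listed ligands. They also leave out the activin receptors ACVR1B (0.0292 ± 0.00096) and ACVR2B (0.00117 ± 0.000074). Both placements hold for the listed members only. The colony stimulating factor receptors, KIT, FLT3, CSF1R and CSF2RA, were low as a list, at percentile 1.3. CSF1R led them at a Ct of 27.6 ± 0.16, and KIT was the lowest at 31.2 ± 0.35. Their ligands lay at percentile 91.4, from FLT3LG at 0.459 ± 0.11 to CSF2 at 0.0767 ± 0.052. In all, 5 of the 23 lists fell outside the central 95% of random lists, where 1.15 would by chance. The call for the colony stimulating factor receptors ended in 5 of the 8 alternatives, without column A among them (percentile 2.96). That for the CC chemokine receptors ended when no Ct limit was set (percentile 3.78) or undetected values were set to a Ct of 40 (percentile 7.04).

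The remaining lists lay within the range of random lists. IL-6 family ligands stood at percentile 92.8 with 4 of 6 detected, from CLCF1 to OSM (0.00156 ± 0.0012), and included IL6 (0.146 ± 0.055) and LIF, whose level of 1.70 ± 1.7 rests on column A (3.67, against 0.652 in B and 0.792 in C). Their receptors lay at percentile 76.4, from OSMR (0.676 ± 0.036) to CNTFR (0.00080 ± 0.00015), and IL6R was at 0.00184 ± 0.00033. The growth factor list, in which the cytokine MIF was counted with EGF, HGF, FGF2 and PDGFC, lay at percentile 88.1. It ran from MIF to EGF (0.00092 ± 0.00068). The growth factor receptor list, in which CD74 was counted with EGFR, IGF1R and PDGFRA, lay at percentile 43.8. It ran from EGFR (2.18 ± 0.24) to PDGFRA (0.00158 ± 0.00074). TNF superfamily receptors lay at percentile 77.5. TNFRSF1A led them at 4.52 ± 0.27 and exceeded TNFRSF13C by 12.29 ± 0.079 cycles. TNF superfamily ligands lay at percentile 64.3, from TNFSF13 (1.49 ± 0.85) to TNFSF14 (0.00157 ± 0.0012). For the common gamma chain and TH2 interleukins the percentile was 28.5, from IL7 (0.361 ± 0.13) to IL9 (0.00104 ± 0.00046). Their receptors lay at 36.8, from IL15RA (0.981 ± 0.10) to IL2R. For the IL-10 and IL-12 family it was 65.0 for the ligands, from IL20 (0.102 ± 0.077) to IL10 (0.00663 ± 0.0055), and 48.6 for the receptors, from IL20RA (0.137 ± 0.0017) to IL12RB1 (0.00209 ± 0.00050). VEGF ligands lay at 27.8 and VEGF receptors at 19.5. Without column C the placement moved to 47.0 for the VEGF ligands, and with the mean to 64.9. It moved to 39.8 without column C for the IL-10 and IL-12 family ligands. With undetected genes of the panel set to a Ct of 40 it moved to 51.8 for the IL-6 family ligands and 21.3 for the growth factor receptors. Under that setting it moved to 32.9 for the VEGF receptors, all 4 of which were detected, so only the random lists changed. With the mean it moved to 11.4 for the VEGF receptors, 21.1 for the CXC and related receptors and 21.95 for the receptors of the common gamma chain and TH2 interleukins. Among lists too short to be placed, IL1B (3.82 ± 1.8) exceeded IL33 (0.270 ± 0.089) in the IL-1 family, IL17A was at 0.00904 ± 0.0047 and its receptor IL17RA at 0.518 ± 0.027, and the interferon receptor IFNGR1 was at 2.21 ± 0.22.

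**Figure D1:**
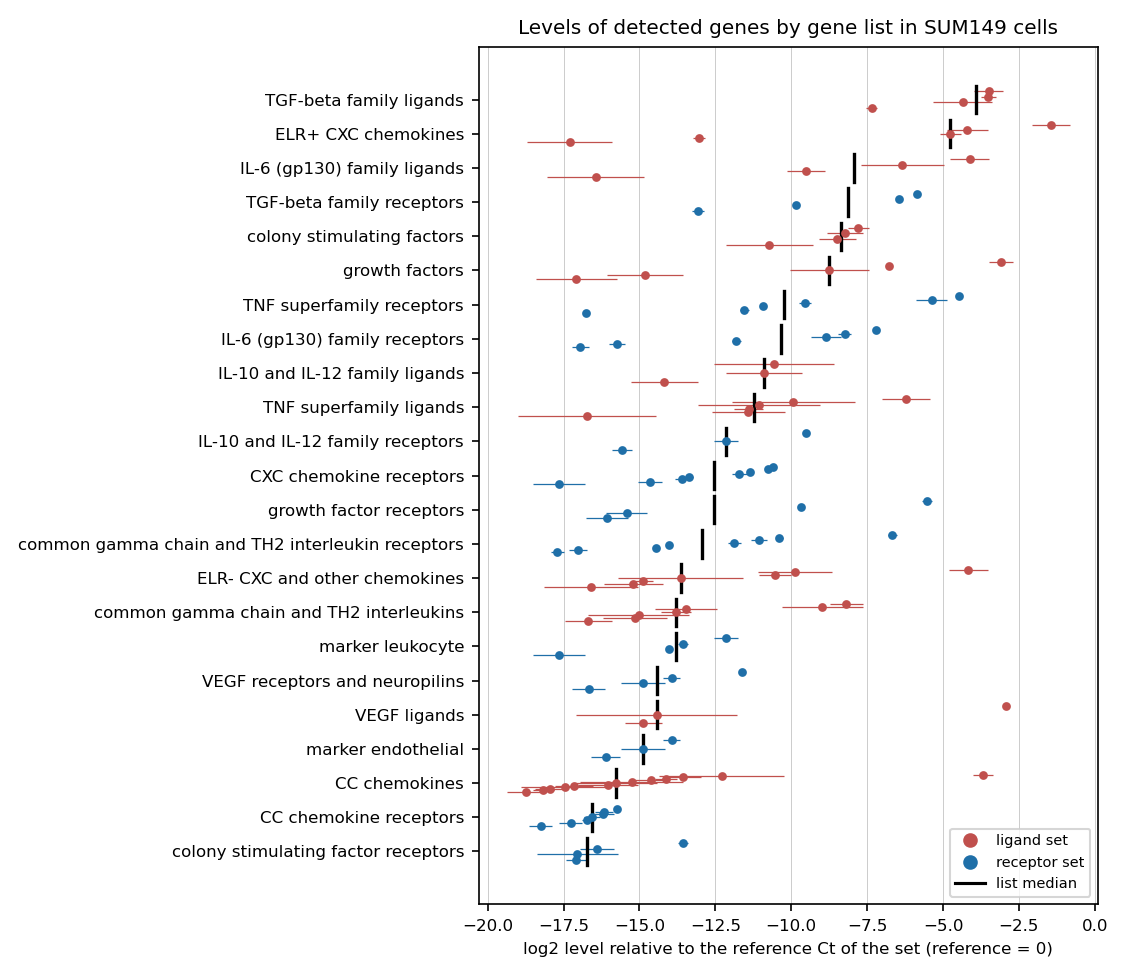
Log2 relative level (x axis, reference = 0) of each detected gene, grouped by the 23 gene lists (y axis), with points for the mean and bars for the SD over columns A, B and C, red for ligands and blue for receptors, and a black line for each list's median. TGF-beta family ligands have the highest median (-3.93) and colony stimulating factor receptors the lowest (-16.72).

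Few markers of other cell types were on the panel, and the 4 leukocyte markers each also belong to another list. The endothelial markers KDR and FLT4 are also in the VEGF receptor list, and PDGFRA is in the growth factor receptor list. The endothelial placement is therefore not separate from that of the VEGF receptors. Endothelial markers KDR, FLT4 and TEK lay at percentile 19.7, with TEK at a Ct of 30.2 ± 0.48. The leukocyte markers lay at percentile 27.2, from IL10RA at a Ct of 26.3 ± 0.40, through CSF1R and IL7R (28.1 ± 0.044), to CX3CR1 at 31.8 ± 0.85. With the mean in place of the median the endothelial markers lay at percentile 9.32 and the leukocyte markers at 10.7, and with undetected genes of the panel set to a Ct of 40 at 32.1 and 41.1. PDGFRA, a fibroblast marker, had a Ct of 30.1 ± 0.69. No marker of epithelial cells was measured.

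Ligands and their matching receptors were set against each other, to ask which ligand transcripts the line holds together with that of a matching receptor gene. A pair holds a single receptor gene, so it does not show that a complete receptor is made. The largest excesses of ligand were those of CCL20 over CCR6 (12.51 ± 0.57 cycles), MIF over CD74 (12.33 ± 1.04), VEGFC over FLT4 (11.95 ± 0.72) and KDR (11.00 ± 0.30), CXCL1 over CXCR2 (10.25 ± 0.54) and IL33, an alarmin, over IL1RL1 (10.09 ± 0.68). Each of these had an adjusted p of 0.00011 by limma. Receptors exceeded ligands most for EGFR over EGF, a difference of -11.55 ± 1.49 cycles for ligand minus receptor (limma adjusted p = 0.00023), and for OSMR over OSM, -9.23 ± 1.67 (0.00054). TNFRSF1A exceeded TNF (-6.60 ± 2.07), CXCR1 exceeded CXCL6 (-6.55 ± 1.51), LTBR exceeded LTB (-6.03 ± 0.060) and IL17RA exceeded IL17A (-5.96 ± 0.67). Their adjusted p-values ran from 0.00023 to 0.0025. Among these pairs CCR6 (mean Ct 30.3), IL1RL1 (32.8), EGF (32.2), OSM (31.6) and CXCL6 (32.4) lay over a Ct of 30. Such values cannot be told apart from background, so the size of those differences is uncertain, which the p-values do not measure.

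Of the 64 pairs, the ligand was higher in 34, the receptor in 18, and 12 did not pass the threshold of limma. All 52 pairs past the threshold had the same direction in 3 of 3 columns. The 34 include IL2 with IL2R, whose rows share a primer name. Both the 34 and the 18 include pairs with a gene at a mean Ct over 30, where background cannot be told apart. In VEGFA with FLT1 both genes lay there. CXCL8 exceeded CXCR1 by 6.55 ± 0.58 cycles and CXCR2 by 7.51 ± 0.57, and IL6 exceeded IL6R by 6.24 ± 0.48. In 6 pairs both genes had a mean Ct under 25, a limit that was not part of the plan. These were TGFB1 with TGFBR1 and with TGFBR2, TGFB2 with TGFBR2, LIF with LIFR, IL15 with IL15RA and CXCL8 with CXCR1. CXCR1 lay just under the limit, at 24.8, so the count depends on it. TGFB1 exceeded TGFBR1 by 2.96 ± 0.55 cycles (limma adjusted p = 0.0027), and TGFB2 against TGFBR2 did not pass with columns paired (1.52 ± 1.03, adjusted p = 0.053) but passed with columns not paired (limma adjusted p = 0.029). VEGFA exceeded FLT1 by 1.80 ± 0.20 cycles (adjusted p = 0.0090) and fell short of NRP2 by -3.25 ± 0.63 (0.0024), and against KDR it did not pass (-0.93 ± 0.37, adjusted p = 0.079). On raw Ct, without the 1.05 cycles between the references of the sets, VEGFA with FLT1 no longer passed (0.75 cycles, limma adjusted p = 0.12), nor did LIF with LIFR (1.46, 0.15) or IL2 with IL2R (1.63, 0.11). On the same scale VEGFA with KDR passed (-1.98, adjusted p = 0.0082), as did CCL7 with CCR2 (-2.53, adjusted p = 0.010), and no called pair changed direction. With a column left out, calls by limma ended for LIF with LIFR (1.51 cycles without A, adjusted p = 0.078, and 3.11 without C, 0.068), IL15 with IL15RA (-1.63 without A, 0.061), TGFB1 with TGFBR2 (2.25 without B, 0.056) and VEGFA with FLT1 (1.69 without B, 0.15), and TGFB2 with TGFBR2 passed without A (2.06, 0.023). Calls with the receptor higher also ended for CXCL5 with CXCR2 (limma adjusted p = 0.13 without A, 0.19 without B) and IL10 with IL10RA (0.066 and 0.22). The same held without B for IL4 with IL4R (0.14) and CCL7 with CCR1 (0.062). Without C, CCL5 with CCR1 (0.029) and CCR5 (0.022), CCL7 with CCR2 (0.026), VEGFD with FLT4 (0.015) and TNFSF12 with TNFRSF12A (0.014) passed.

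Levels of different genes rest on different primers, and against a minimum difference of 2 cycles limma retained 39 of the 64 pairs, 28 with the ligand and 11 with the receptor higher. TGFB1 with both receptors (adjusted p = 0.063 and 0.30), LIF with LIFR (0.38), IL15 with IL15RA (0.43) and VEGFA with FLT1 (0.87) were not among them. Of the 77 measured pairs, 13 could not be tested because 1 gene was not detected. In 11 of these the ligand was not called detected and the receptor was. Among them were CXCL12 with CXCR4, IFNG with IFNGR1, IGF1 with IGF1R and IL11 with IL11RA. Not all of these ligands lacked a value. CXCL12, CCL8, CCL15, CCL17 and CCL26 had a Ct in every column, within the limit of 35 in some columns and over it in others.

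**Figure D2:**
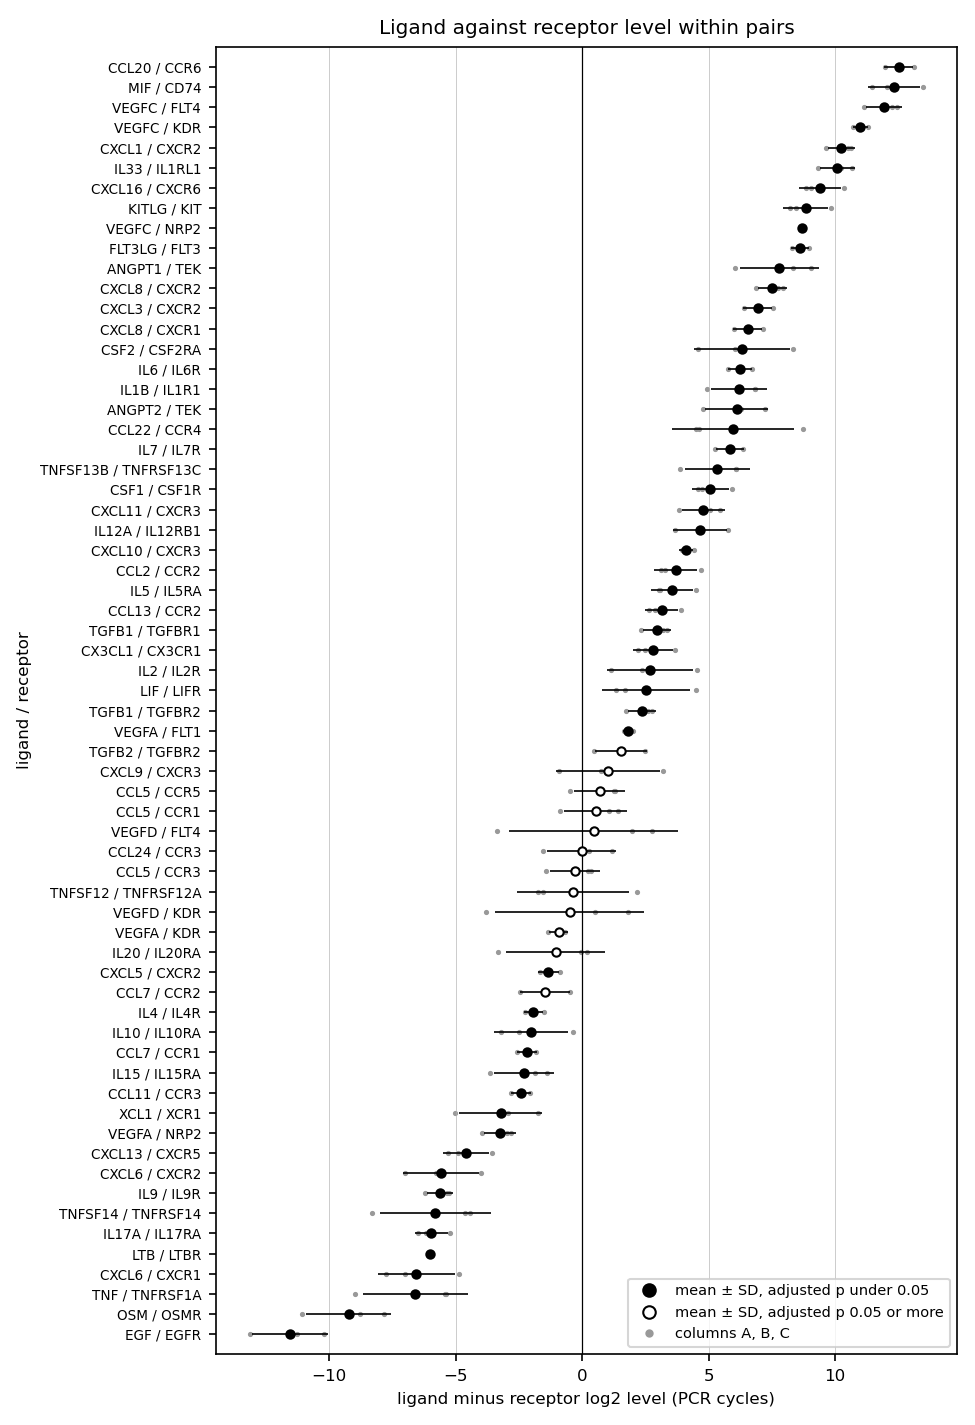
Difference in log2 level between ligand and receptor (x axis, PCR cycles) for the 64 pairs (y axis), with small grey points for columns A, B and C, large points for the mean and bars for the SD; filled points have a limma adjusted p under 0.05. Differences range from 12.51 cycles for CCL20 with CCR6 to -11.55 for EGF with EGFR.

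Taken as classes over all detected genes, ligands and receptors were not separated by the test of their medians. The median log2 relative level was -11.07 for 81 ligands and -12.29 for 76 receptors, a difference of 1.23 log2 units over genes and of 1.27 ± 0.20 over columns (permutation test over genes, two-sided p = 0.38). The difference of means was 1.51 log2 units (permutation p = 0.029), and at a Ct limit of 32 the difference of medians was 2.05 (permutation p = 0.027). Both include the 1.05 cycles between the references of the sets, and neither was tested without them. A shared Ct limit also keeps receptors down to relative levels 1.05 cycles lower than ligands. Without the separate reference values of the 2 sets the medians differed by 0.18 cycles, at Ct values of 26.2 and 26.4. With undetected genes set to a Ct of 40 the difference was -0.39.

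Columns agreed closely across genes, and more so for receptors. Across 157 genes, which are not independent replicates, Pearson's r was 0.982 for A with B, 0.952 for A with C and 0.958 for B with C (Spearman's rho 0.972, 0.948 and 0.947). The median SD between columns was 0.779 cycles for ligands and 0.212 for receptors, a ratio of 3.68 (permutation test over genes, two-sided p = 2e-05, the smallest that the resamples can give). Without column C the ratio was 2.46, and without A or B it was 5.20 or 4.64 (permutation p = 2e-05 each). VEGFD, TNFSF14 (SD 2.27 cycles) and CCL22 (2.06), all ligands, had the largest SDs among detected genes. An SD over 1 cycle was found for 32 of 81 ligands and 1 of 76 receptors, which was CSF2RA.

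**Figure D3:**
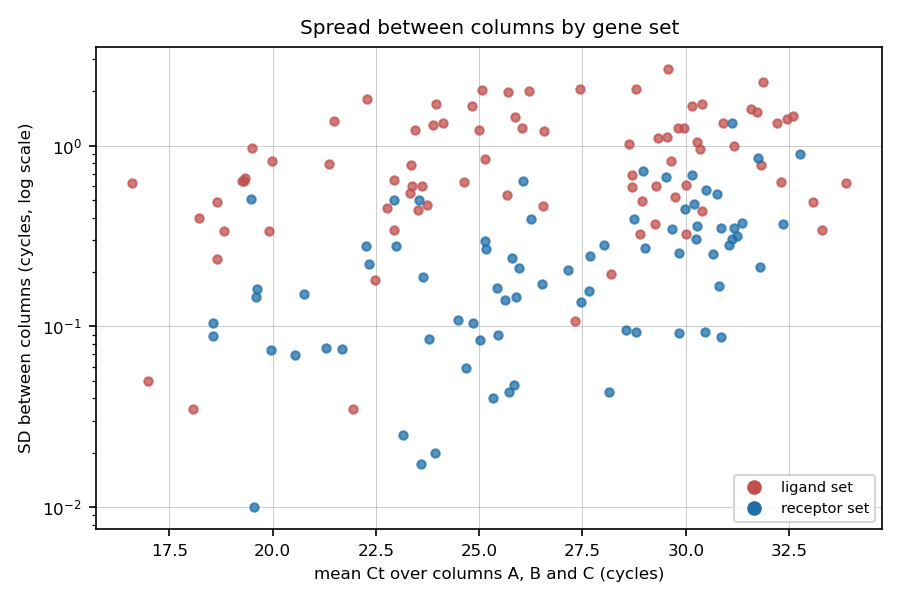
SD between columns A, B and C (y axis, cycles, log scale) against mean Ct (x axis, cycles) for each detected gene, red for the 81 ligands and blue for the 76 receptors. The median SD is 0.779 cycles for ligands and 0.212 for receptors.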

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

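The unpaired test, the raw Ct settings, the classes taken from the lists alone, the background from the same set and the ratio of SDs with a column left out were chosen after seeing the data. The number of detected genes, 157, was 139 at a Ct limit of 32 and 168 with no limit. Both lie within the set bound of 1.5 times, but a panel of 178 genes cannot pass it upward, so this shows little about stability. The 52 pairs past the threshold became 39 to 59 under the other settings that keep all columns, and 46 to 60 with a column left out. On raw Ct 3 calls were lost and 2 gained, and without pairing 2 were gained and 0 lost. All 12 pairs with the largest differences (6 in each direction) kept their direction and their call wherever both genes were still detected. Over the 12 and the other pairs named, the call held in 270 cases, was lost in 15 and gained in 10. Pairs named only because their call changed with a column left out are not in these counts. Among single lists 176 placements kept their side of the central range and 8 lost it (several percentiles within that range moved by over 1.5 times). Among levels of single named genes 243 stayed within 1 SD and 93 did not, all of the 93 under panel median normalization or the factor of 1.9, which change the scale. Leaving out 1 of 3 columns cannot move a mean by 1 SD, and a Ct of 40 for undetected values leaves detected genes unchanged. Those settings could give no other result, so the 243 do not measure stability. For ligands against receptors, the difference of means passed (1.51), and the difference of medians passed at a Ct limit of 32 (2.05, permutation p = 0.027). The difference of medians was 0.08 with no limit, and turned to -0.39 (permutation p = 0.71) with undetected values at a Ct of 40. Leaving out a column gave 0.79 (without B) to 1.00. All of these include the 1.05 cycles between the references of the sets. The number of lists outside the central range fell from 5 to 3 with no Ct limit and to 3 with values set to 40. The median log2 level of detected genes, -11.87, became -10.99 at 1.9 per cycle, -13.55 with values set to 40, and 0.10 after normalization to the panel median, which moves the zero point by construction, drops the offset between the sets and changed the order of some genes (Spearman's rho 0.991); it ran from -12.12 (without C) to -11.77 without a column. The median SD between columns, 0.438 cycles, was 0.36 at a Ct limit of 32 and 0.24 (without C) to 0.39 with a column left out; without A it was 0.29. An amplification factor of 1.9 scales every difference alike and leaves the tests unchanged by construction. The causes of the other changes were not tested. With 3 columns and no primer efficiencies, small differences between genes are the least certain.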

Other observations

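All genes and tests in this part were chosen after the values were seen. Several abundant transcripts belonged to none of the lists. CRLF1, a secreted partner of CLCF1, had a relative level of 2.29 ± 0.016, so both members of that cytokine complex were among the abundant genes, while their receptor CNTFR was at a Ct of 31.0 ± 0.28. The matricellular proteins CTGF (0.520 ± 0.15) and NOV (0.311 ± 0.088), endothelin genes EDN1 (0.484 ± 0.23) and EDN2 (0.313 ± 0.23) with the receptor EDNRA (0.188 ± 0.0033), and the WNT receptors FZD4 (0.351 ± 0.065) and FZD1 (0.213 ± 0.042) all had mean Ct values under 25. IL32 was at 1.03 ± 0.77. BDNF, a neurotrophin, was at 0.371 ± 0.16, against 0.00070 ± 0.00015 for its receptor NTRK2.

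Column C stood apart for a part of the ligands. Where A and B agreed within 1 cycle, C was over 2 cycles later than their mean for 11 ligands, including TNF (24.95, 25.14 and 28.53), IL32, CSF2, FGF2 and EDN2, and over 2 cycles earlier for 5, CCL22, TNFSF12, CXCL9, INHBB and HGF. By the same measure A stood apart for 7 ligands and B for 1, and no column did so for any of the 76 detected receptors.

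The wider spread of the ligand set was not explained by low template. Among genes of like Ct the ratio of median SDs, ligand over receptor, was at least 3.64 in each of 4 Ct ranges up to 33 cycles. Nor was it a shift of whole columns, since the ratio was 3.59 after the column medians of each set were removed. The spreads of the sets overlapped: an SD under 0.2 cycles was found for 6 of 81 ligands and 36 of 76 receptors. The receptor columns may be repeat wells of 1 cDNA and the ligand columns separate cultures; this cannot be told apart from a wider variation of cytokine transcripts between cultures, which was not tested, because the ratio over all detected genes, 3.68 (2.46 without column C), would follow from either and the labels do not say what a repeat was. If the sets came from different cDNA, the pairing of columns between ligand and receptor carries no meaning; the test without pairing called 54 of 64 pairs.

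FSHB, a hormone gene known from the pituitary, amplified at a Ct of 17.0 ± 0.050, earlier than every gene but ACTB and CXCL1, while its receptor FSHR had a Ct of 29.97 ± 0.44. Genomic DNA in the cDNA is argued against: 13 panel genes were listed as having coding regions not interrupted by introns, by textbook knowledge, so that primers within them amplify DNA as well, and the earliest of them, FZD1, came 6.0 cycles after FSHB. Of these 13, BDNF alone belongs to the ligand set, 6.36 cycles after FSHB. A product other than FSHB may account for the value and cannot be told apart from true expression, because only 1 row of the panel measures the gene. No biological explanation was tested.

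The 7 CC chemokine receptors, typical of leukocytes, lay close together, between a Ct of 29.8 and 32.3 (SD of their means 0.838 cycles). Such a band may reflect a background of genomic DNA. The latest of the 13 genes listed with uninterrupted coding regions was CCR4, at a mean Ct of 32.3, but CCR4 and other receptors of the band are among the 13, so their detection decides nothing. Genomic DNA cannot be told apart from low expression without a control lacking reverse transcriptase, and levels near or beyond a Ct of 30 in genes of this kind are open in that respect. No biological explanation was tested.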
